A study of Mus musculus with 8 samples.

How the data were processed

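RNA from sciatic nerves was extracted with RNeasy Mini columns and DNase, and stranded polyadenylated libraries were made from 250 ng of RNA, per the labels. The deposited values are estimated counts per gene, which the authors made with STAR and Salmon against the mouse genome GRCm38, per the submitters' processing notes; aligner settings, versions and the annotation release are not given in the sources used here. Of these values 8.29% were not whole, and all were rounded to whole numbers, which moved a library total by at most 0.000113%. The table held 55487 Ensembl gene identifiers, of which 55141 matched a symbol and 346 did not. Replicates of a group differed more than counting alone gives, with a chi-square per degree of freedom between 3.98 and 18.6 over gene pairs with at least 10 summed counts.

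Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 15056, and normalized by trimmed mean of M values (TMM). Groups were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. A total of 37 gene lists for pathways, cell types and quality were fixed from general knowledge before the data were examined, as were the design, the alternatives and the naming rule. Lists with at least 5 tested members were tested by camera on log CPM with a prior count of 2 and a preset correlation of 0.01, again with a correlation estimated per list, and by fry. The mean log CPM of each list was also compared by a two-sided exact permutation over libraries, whose smallest possible p is 0.0286.

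Cdk7 and Cnp were always named. The 8 genes with the largest fold change in each direction were named among those called, with a mean of at least 2 CPM in the higher group and all 4 CNP-Cdk7cKO values outside the Ctrl range, leaving out Xist, Tsix, Y-linked and unnamed genes. From each list, up to 4 called members with the smallest p were named, or the 2 with the highest mean CPM where none was called. Any member of the myelin, cholesterol, fatty acid and sphingolipid lists could be named. The rule gave 123 genes; others are marked where they appear. Libraries were called male or female from Xist and 4 Y-linked genes, since sex was not taken from the labels.

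The alternatives were RLE factors, TMM without muscle, erythroid, adipocyte and mitochondrial genes, no count filter, a filter of 1 CPM in 4 libraries, DESeq2, limma-voom with quality weights, the replicate number as a block, the skeletal muscle markers, Xist or the first surrogate variable as a covariate, each library left out in turn, and the set tests above. The comparison of female libraries alone was chosen after the data were seen.

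The steps were tested on simulated counts with 50 genes planted at each fold. Among 15056 simulated genes, 14% of the planted genes were recovered at 1.25-fold, 72% at 1.5-fold, 86% at 2-fold and 92% at 3-fold, and 6 other genes were called. A list planted at a log2 fold change of -0.4 was called by camera (adjusted p = 9.43e-40, and 0.000202 with an estimated correlation), and 0 of the other lists were. The planted list was cholesterol synthesis, and all simulated genes were drawn independently of each other. In the data that list had an estimated correlation of 0.368, so the simulation does not show how camera treats correlated members.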

Results

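RNA was measured by sequencing of polyadenylated transcripts from whole sciatic nerves of mice at postnatal day 6, an age at which Schwann cells, the glia that wrap peripheral axons, sort axons and form myelin. The 8 libraries fall into 2 groups of 4. Control animals (Ctrl) had 2 unmodified Cnp alleles and 2 floxed Cdk7 alleles. Conditional knockout animals (CNP-Cdk7cKO) had the same floxed Cdk7 alleles and Cre recombinase at 1 Cnp allele, which is active in Schwann cells. The smallest library held 16897242 estimated counts (Ctrl 1) and the largest 21527891 (Ctrl 3). The table listed 55487 genes, of which 15056 had enough counts to be tested. Expression is given in CPM (counts scaled to library size), and fold changes are CNP-Cdk7cKO over Ctrl. Adjusted p-values for genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all 15056 genes. The labels do not say in so many words that each library came from a separate animal, so the p-values measure the spread between these libraries.

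The targeted gene was lower in each knockout library than in any control library. Cdk7, on chromosome 13 from 100702631 to 100730939 (GRCm38), encodes the catalytic subunit of the kinase that activates other cyclin-dependent kinases and that, within the general transcription factor TFIIH, phosphorylates RNA polymerase II. It measured 21.7, 22.2, 21.4 and 20.6 CPM in Ctrl 1 to 4 and 9.62, 11.8, 12.7 and 12.1 CPM in CNP-Cdk7cKO 1 to 4. The group means were 21.5 ± 0.70 and 11.6 ± 1.35 CPM (SD, n = 4), a log2 fold change of -0.89 ± 0.09 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000181). Counts were summed over the whole gene, so they do not separate a transcript without the floxed exons from an intact one, and the nerve also holds cells other than Schwann cells. Cnp, a phosphodiesterase gene of myelin-forming glia whose locus carries Cre in the knockout, fell from 3134 ± 137 to 1389 ± 61.6 CPM (log2 fold change -1.17 ± 0.04, edgeR quasi-likelihood adjusted p = 3.98e-07). Of the 10 measured subunits of the Cdk7 kinase complex and TFIIH, Cdk7 was the 1 that changed, also when adjusted over the list alone; the list had a median log2 fold change of 0.08 and a mean of -0.03, and camera did not call it (adjusted p = 0.682). Its partners Ccnh and Mnat1 measured 18.1 and 12.9 CPM in Ctrl and 16.9 and 13.1 CPM in CNP-Cdk7cKO (both named after their values were seen). Among 25 genes of RNA polymerase II and its elongation kinases, 2 rose and 0 fell, the same number as when adjusted over the list alone. These were Polr2a, the largest polymerase subunit, which rose from 110 ± 3.05 to 253 ± 16.5 CPM (log2 fold change 1.21 ± 0.05), and Hexim1, an inhibitor of the elongation kinase P-TEFb (0.30 ± 0.06). For this list, camera gave an adjusted p of 0.0374, with an adjusted p = 0.29 with an estimated correlation, and the preset call also ended with Xist or the muscle markers as a covariate (adjusted p = 0.227 and 0.261), in the female libraries alone (adjusted p = 0.239), and without Ctrl 2 or CNP-Cdk7cKO 4 (adjusted p = 0.084 and 0.173).

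**Figure D1:**
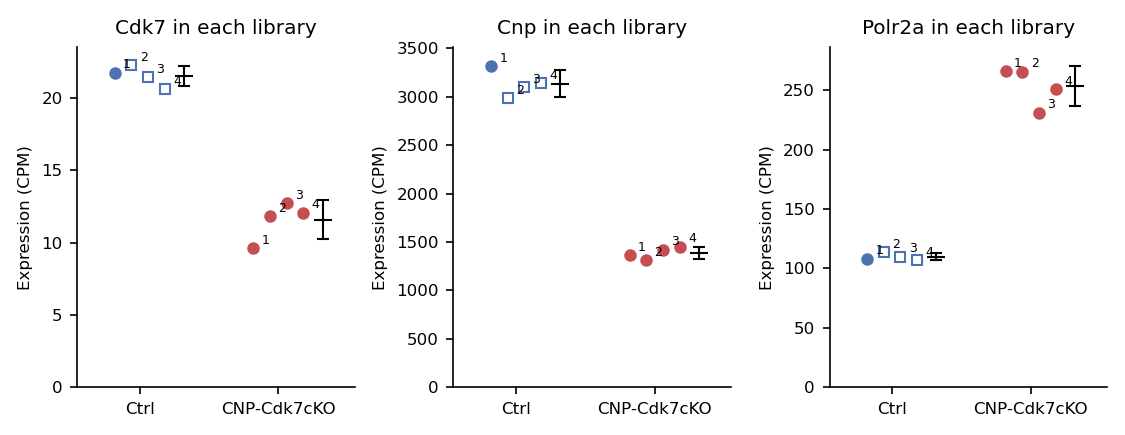
Expression of Cdk7, Cnp and Polr2a in CPM (vertical axis, from 0) in each of the 4 Ctrl and 4 CNP-Cdk7cKO libraries, numbered by replicate; open squares are libraries with Y-linked counts, and black bars are mean ± SD. Cdk7 sits between 20.6 and 22.2 CPM in Ctrl and between 9.62 and 12.7 CPM in CNP-Cdk7cKO.

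In CNP-Cdk7cKO nerves most genes of cholesterol synthesis and many of fatty acid synthesis and of the myelin proteins were lower, and most p53 target genes, Ccnd1 and many inflammatory cytokine genes were higher. These are calls of single genes; as lists, none was called by camera with an estimated correlation. In all, 763 genes were higher and 994 lower in CNP-Cdk7cKO, 59 and 195 of them by at least 2-fold. The largest rises under the naming rule were in Pmaip1, a pro-apoptotic p53 target (0.19 ± 0.07 to 3.97 ± 0.99 CPM), and in Ano3, an anoctamin (log2 fold change 4.12). Klhdc7a (3.50), the ciliary transcription factor Foxj1 (3.06), the ectodysplasin receptor gene Eda2r (2.51), the argininosuccinate synthase gene Ass1 (2.38), the long non-coding RNA Pvt1 (2.03) and the spindle gene Psrc1 (1.80) followed. Foxj1 went from 1.89 ± 0.48 to 15.6 ± 1.49 CPM and Psrc1 from 11.5 ± 1.57 to 40.3 ± 4.31 CPM. The 8 largest falls were in genes of skeletal muscle: Myh2 (-4.99), Myl2 (-4.91), Myl3 (-4.81), Myh3 (-4.80), Mb (-4.51), Lmod2 (-4.34), Lmod3 (-4.12) and Ckmt2 (-4.02). Groups of 2838 tested genes (18.9%) did not overlap, against 2.86% by chance. Without Ctrl 2 the test called 470 genes higher and 653 lower, and without Ctrl 3 it called 500 and 708.

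The groups also differed in sex and in muscle transcripts. Xist, transcribed from the inactive X chromosome of females, measured 295 CPM in Ctrl 1 and between 285 and 334 CPM in the 4 CNP-Cdk7cKO libraries, but 0.10, 0.09 and 0 CPM in Ctrl 2, 3 and 4. The summed expression of 4 Y-linked genes was 92.3 to 106 CPM in Ctrl 2 to 4, 0 in Ctrl 1 and at most 0.20 CPM in the knockout libraries. By these counts Ctrl 2 to 4 were male, and Ctrl 1 and all CNP-Cdk7cKO libraries were female. Skeletal muscle markers took 0.253 ± 0.245% of counts in Ctrl and 0.0387 ± 0.0287% in CNP-Cdk7cKO (SD, n = 4; two-sided exact permutation p = 0.0571), with 0.607% in Ctrl 4 and 0.0622% in Ctrl 1. Of the 20 muscle markers, 17 fell (19 adjusted over the list alone) and 0 rose, with a median log2 fold change of -2.67; the fall was called by camera (adjusted p = 2.17e-08), but not with an estimated correlation (adjusted p = 0.391). Fewer muscle markers fell without Ctrl 2 (8), Ctrl 4 (10), or CNP-Cdk7cKO 1, 3 or 4 (5 each), and 4 fell by limma-voom. With Xist as a covariate 0 of the 17 falls passed and the median was -0.61; Ctrl 1 differed from the male controls by a median of -1.85. With Xist as a covariate, 76 genes were called higher and 167 lower, and 1747 of the 1757 genes called without it kept their sign. With the muscle markers as a covariate, 158 were called higher and 228 lower, and 1731 kept their sign. Restricted to the female libraries, a comparison chosen after the data were seen in which Ctrl 1 is the lone control and is assumed to vary like the other group, the counts were 40 and 77, and 1755 genes kept their sign. With Ctrl 1 as the 1 female control, the fit with Xist rests on that library. Xist and group were correlated, which widened the standard error of a fold change 1.58 times.

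**Figure D2:**
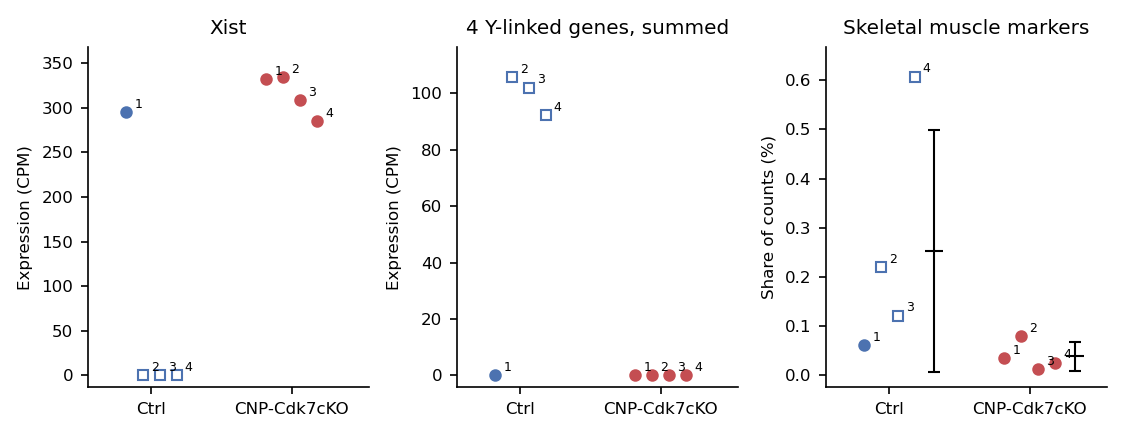
Xist in CPM, the sum of 4 Y-linked genes in CPM, and the share of counts on 20 skeletal muscle markers in percent, in each library (replicate numbers beside the points; open squares, libraries with Y-linked counts; black bars in the muscle plot, mean ± SD). Ctrl 2 to 4 carry Y-linked counts of 92.3 to 106 CPM, and Ctrl 4 has the highest muscle share, 0.607%.

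Cholesterol synthesis genes were lower in the knockout nerves along nearly the whole pathway. Of 25 measured members, 23 fell and 0 rose; adjusted over the list alone, 24 fell and 1 rose. Lss, which closes the sterol ring as lanosterol synthase, fell from 258 ± 10.6 to 145 ± 9.76 CPM (SD, n = 4; log2 fold change -0.83 ± 0.06 SE, edgeR quasi-likelihood adjusted p = 2.51e-05). Hmgcs1 (-0.80 ± 0.11) fell at the start of the pathway, and Fdps (-0.67 ± 0.04) and the sterol demethylase gene Cyp51 (-0.66 ± 0.05) further along it. Insig1, a sterol-sensing regulator of the pathway (-0.76 ± 0.07), and Srebf2, the transcription factor of sterol synthesis (-0.22 ± 0.04), also fell. Dhcr7 was among the 2 members that did not pass (-0.19, edgeR quasi-likelihood adjusted p = 0.0631). The median log2 fold change of the list was -0.45, and camera with its preset correlation called it lower (adjusted p = 2.07e-18), but not with an estimated correlation (adjusted p = 0.111). The mean expression of the list did not overlap between the groups (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow, and 0.0661 adjusted over 37 lists). The same exact p was reached by lists that camera did not call, such as sphingolipid synthesis and the basal lamina. It therefore does not set the cholesterol list apart. With Xist as a covariate 17 of the 23 falls still passed and the median was -0.55; with the muscle markers as a covariate 18 members were called lower.

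Fatty acid synthesis genes fell alongside, with 14 of 26 measured members lower and 0 higher (17 and 0 adjusted over the list alone). Scd1 and Scd2, desaturases that make oleate, fell from 434 ± 64.0 to 221 ± 25.2 CPM and from 3263 ± 274 to 2180 ± 250 CPM (log2 fold changes -0.97 ± 0.11 and -0.58 ± 0.08). The acetyl-CoA synthetase gene Acss2 (-0.81 ± 0.07), the elongase gene Elovl6 (-0.45 ± 0.04), the desaturase genes Fads2 (-0.47 ± 0.05) and Fads6 (-1.08 ± 0.11), Acaca (-0.38) and the fatty acid synthase gene Fasn (-0.33) were among them. Srebf1 had a log2 fold change of -0.23 that did not pass (edgeR quasi-likelihood adjusted p = 0.051). The list had a median of -0.29 and camera called it (adjusted p = 7.35e-09), but not with an estimated correlation (adjusted p = 0.111); 9 of the 14 falls still passed with Xist as a covariate (list median -0.33). Of 30 genes of lipid uptake, transport and storage, 9 fell and 1 rose (13 and 3 adjusted over the list alone). Abca8b (-0.72), the long-chain acyl-CoA synthetase gene Acsl3 (-0.55) and the cholesterol exporter gene Npc1 (-0.24) fell, and the apolipoprotein gene Apoe rose (0.34). Camera called this list lower (adjusted p = 0.0021), but not with an estimated correlation (adjusted p = 0.111), and 2 of its 10 calls still passed with Xist as a covariate, where the list median went from -0.20 to -0.14. Without CNP-Cdk7cKO 1, 5 members of the uptake list fell and 2 rose. In sphingolipid and galactolipid synthesis 3 of 20 members fell and 0 rose, also when adjusted over the list alone: the ceramide synthase gene Cers4 (-0.45), the ceramide kinase gene Cerk (-0.39) and Ugt8a, which makes galactosylceramide (-0.36). Without Ctrl 1, 2 members of that list fell and 1 rose. Fa2h and Gal3st1 of the same list measured 679 and 282 CPM in Ctrl and 665 and 278 CPM in CNP-Cdk7cKO. Camera gave this list an adjusted p of 0.0872. Among 31 genes of glycerophospholipid and triglyceride synthesis 2 rose (Agpat4, 0.25; Dgat2, 0.31) and 2 fell (Pcyt2, -0.24; Pisd, -0.16), against 3 and 2 adjusted over the list alone, and camera did not call the list (adjusted p = 0.754). At most 2 members rose and 2 fell in that list with any library left out, and 0 rose without Ctrl 2, Ctrl 3 or CNP-Cdk7cKO 1. Fatty acid oxidation had 1 rise (Cpt1c, 0.61) and 3 falls (Pdk4, Acadm, Acadl) among 26 members, the same adjusted over the list alone (camera adjusted p = 0.835); without Ctrl 4, 3 rose and 1 fell, and without CNP-Cdk7cKO 3, 1 rose and 1 fell. Pdk4 was highest in Ctrl 4, the library with most muscle transcripts (18.9 CPM, against 5.63 CPM in Ctrl 1). In the oxidation list 0 of the 4 calls passed with Xist as a covariate, and 1 rise and 1 fall were called with the muscle markers as a covariate.

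**Figure D3:**
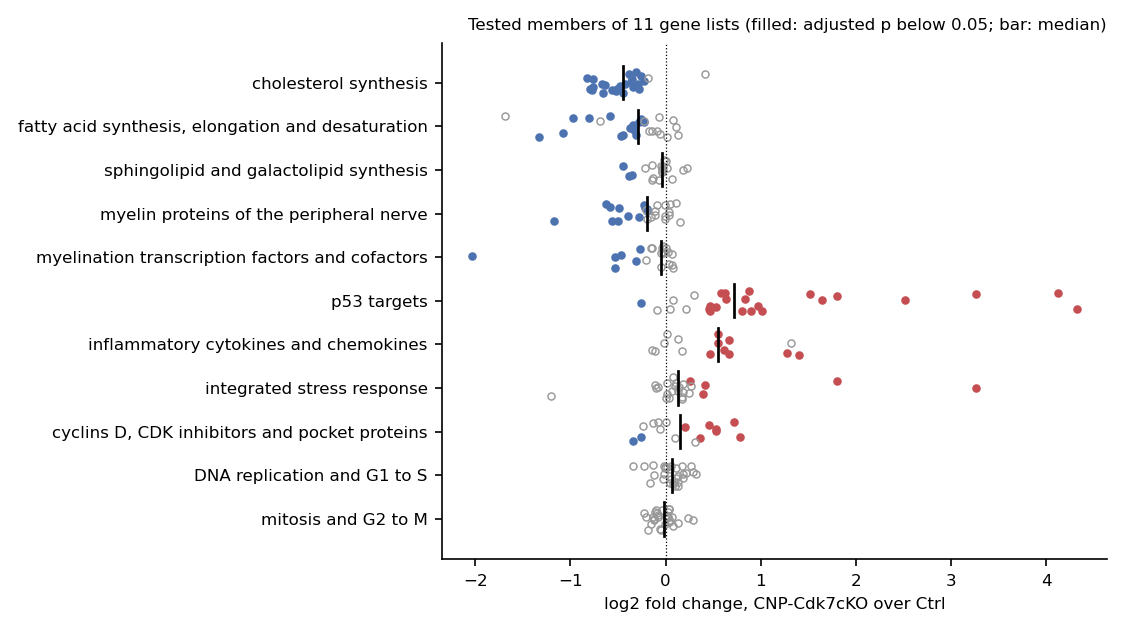
Log2 fold change, CNP-Cdk7cKO over Ctrl, of every tested member of 11 of the fixed gene lists; filled points passed the test (red, higher; blue, lower), open points did not, and black bars are list medians. The median is -0.45 for cholesterol synthesis, -0.29 for fatty acid synthesis and 0.72 for p53 targets, and 0 members passed in the DNA replication and mitosis lists.

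Myelin protein genes were split between members that fell and members that did not pass. Of 26 measured members, 12 fell and 0 rose (14 and 0 adjusted over the list alone). Cnp (-1.17) is among the 12, and its locus carries Cre in the knockout, so its fall cannot be told apart from the altered allele. It is also part of the list median and the camera call below. The tight junction gene Cldn19 fell from 2157 ± 76.2 to 1643 ± 18.7 CPM (SD, n = 4; log2 fold change -0.39 ± 0.04 SE, edgeR quasi-likelihood adjusted p = 0.000105). The connexin gene Gjc3 (-0.50), Mbp (-0.22) and Pmp22 (-0.19) also fell. Periaxin (Prx) measured 7669 ± 403 CPM in Ctrl and 7940 ± 443 CPM in CNP-Cdk7cKO, and Mag 996 ± 36.6 and 933 ± 24.8 CPM, neither of which passed. The list median was -0.19, and camera called it lower (adjusted p = 1.13e-06), but not with an estimated correlation (adjusted p = 0.199). With Xist as a covariate 7 of the 12 falls still passed, and the median was -0.25. A set of 9 pan-Schwann markers, chosen after the data were seen, had a median of -0.27, against -0.19 for the myelin list and -0.29 for the fatty acid list.

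In the list of myelination transcription factors and cofactors, 6 of 21 members fell and 0 rose (7 and 0 adjusted over the list alone). The list also holds Lgi4 and Adgrg6, which are not transcription factors or cofactors and are both among the 6 falls. The retinoid X receptor gene Rxrg fell most, from 16.5 ± 1.75 to 4.03 ± 1.24 CPM (log2 fold change -2.03 ± 0.18). Lgi4 (-0.53 ± 0.05), the adhesion receptor gene Adgrg6 (-0.47 ± 0.08), which Schwann cells need to start myelination, and Pou3f1 (-0.31 ± 0.06) fell too. Egr2, the master regulator of myelination, measured 262 ± 18.3 CPM in Ctrl and 257 ± 16.5 CPM in CNP-Cdk7cKO, and Sox10 735 ± 52.95 and 665 ± 29.7 CPM; neither passed (edgeR quasi-likelihood adjusted p = 0.804 and 0.119; both genes were named after their values were seen). Camera called the list lower (adjusted p = 0.00748), but not with an estimated correlation (adjusted p = 0.391), and 2 of the 6 falls still passed with Xist as a covariate, where the list median went from -0.05 to -0.08. Among 20 genes of immature and repair Schwann cells 4 rose and 3 fell, as when adjusted over the list alone. The matrix gene Tnc went from 55.9 to 110.2 CPM (0.98 ± 0.08), and Igfbp2 (0.75) and Cdkn2b (0.72) rose, while Cdh2 fell (-0.42). The median of this list was -0.05, its mean 0.05, and camera did not call it (adjusted p = 0.917). Markers of non-myelinating Remak Schwann cells fell in 4 of 9 members (6 adjusted over the list alone) and rose in 0: Cadm2 (-0.91), Gfra3 (-1.11), L1cam (-0.47) and Cdh2. Camera called that list (adjusted p = 0.00244), but not with an estimated correlation (adjusted p = 0.199), and 0 of the 4 falls passed with Xist as a covariate, where the list median went from -0.23 to -0.40 under the wider standard error. Among 29 adhesion genes of nodes, paranodes and internodes 7 fell and 1 rose (10 and 1 adjusted over the list alone), with falls in Cldn19, Cadm2, the epithelial cadherin gene Cdh1 (-0.34) and Cadm1 (-0.55). That list was called by camera (adjusted p = 0.00777), but not with an estimated correlation (adjusted p = 0.451), and 1 of its 8 calls passed with Xist as a covariate, where the list median went from -0.06 to -0.14. Of 25 genes of the Schwann cell basal lamina and its receptors 6 fell and 0 rose (7 and 2 adjusted over the list alone). They included Dtna (-0.65), the laminin receptor subunit Itga6 (-0.23) and Dmd (-0.50); camera did not call the list (adjusted p = 0.342). Without CNP-Cdk7cKO 1, 2 members fell, without Ctrl 1, 4 fell and 1 rose, and by limma-voom 5 fell and 3 rose. In the neuregulin, PI3K and mTORC1 list 5 of 26 members fell and 1 rose (5 and 2 adjusted over the list alone). The neuregulin receptor gene Erbb3 fell (-0.42 ± 0.06), as did Pik3r1 (-0.29) and Sos1 (-0.25), and its ligand gene Nrg1 rose from 0.20 ± 0.12 to 1.45 ± 0.31 CPM (2.85 ± 0.36). The median of that list was -0.03, its mean 0.05, and camera did not call it (adjusted p = 0.291). Its falls numbered 2 without Ctrl 2, CNP-Cdk7cKO 2 or CNP-Cdk7cKO 4 and 3 whichever other library was left out, and 2 members rose without Ctrl 3. With Xist as a covariate 1 of the 6 calls passed, a fall, so Nrg1 lost its call, while all 6 kept their sign.

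Targets of the tumour suppressor p53 were higher in the knockout nerves. Of 26 measured members, 20 rose and 1 fell, also when adjusted over the list alone. Sesn2, a stress-induced regulator of mTORC1, rose from 8.97 ± 0.51 to 31.2 ± 3.37 CPM (SD, n = 4; log2 fold change 1.80 ± 0.09 SE, edgeR quasi-likelihood adjusted p = 2.18e-06). Pmaip1 (4.32 ± 0.31), the exonuclease gene Aen (0.89 ± 0.08), Ephx1 (1.01 ± 0.09), Gdf15 (3.26 ± 0.47) and the cell cycle inhibitor gene Cdkn1a (0.53 ± 0.09) rose, the last from 414 ± 36.1 to 599 ± 70.4 CPM. The member that fell was Sesn1 (-0.26), named after its value was seen. The list median was 0.72, and camera called it higher (adjusted p = 1.03e-17), but not with an estimated correlation (adjusted p = 0.097). Mean expression of the list did not overlap between groups (two-sided exact permutation p = 0.0286, adjusted over 37 lists 0.0661). Lists that camera did not call, such as sphingolipid synthesis and the basal lamina, reached the same exact p. It therefore does not set the p53 list apart. With Xist as a covariate 13 of the 21 calls still passed with a median of 0.64, and with the muscle markers as a covariate 16 members were called higher and 0 lower.

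Of 16 D-type cyclins, their kinases, inhibitors and pocket proteins, 7 rose and 2 fell (7 and 3 adjusted over the list alone). Ccnd1, the cyclin that starts the passage through G1, rose from 476 ± 11.7 to 819 ± 65.8 CPM (0.78 ± 0.06), and Ccnd3 (0.36), Cdk6 (0.46) and Cdkn1a rose with it; 3 of the 9 calls passed with Xist as a covariate (list median 0.15 without it and 0.21 with it), and 1 member in place of 2 fell without Ctrl 2 or CNP-Cdk7cKO 2. Camera called this list (adjusted p = 0.0374), but not with an estimated correlation (adjusted p = 0.179), with the replicate block (adjusted p = 0.0662), with Xist or muscle as a covariate (adjusted p = 0.0621 and 0.138), in the female libraries alone (adjusted p = 0.0931), or without Ctrl 2 or CNP-Cdk7cKO 3 (adjusted p = 0.0505 and 0.0923). Genes of DNA replication and mitosis showed few calls in any setting. Of 30 members in each list, 0 rose and 0 fell by edgeR, DESeq2 and limma-voom, also in edgeR when adjusted over the list alone; at an unadjusted p under 0.05 edgeR had 2 replication genes and 1 mitosis gene higher and 0 lower. With the replicate block edgeR called 1 gene higher in each list, without Ctrl 4 it called 1 replication gene higher, and without CNP-Cdk7cKO 2 it called 1 mitosis gene higher. Pcna measured 72.2 ± 3.18 CPM in Ctrl and 76.2 ± 8.18 CPM in CNP-Cdk7cKO, Mki67 73.5 ± 6.23 and 62.7 ± 13.3 CPM, and Top2a 65.3 ± 4.45 and 65.0 ± 11.2 CPM. Camera gave adjusted p-values of 0.304 for replication and 0.58 for mitosis.

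**Figure D4:**
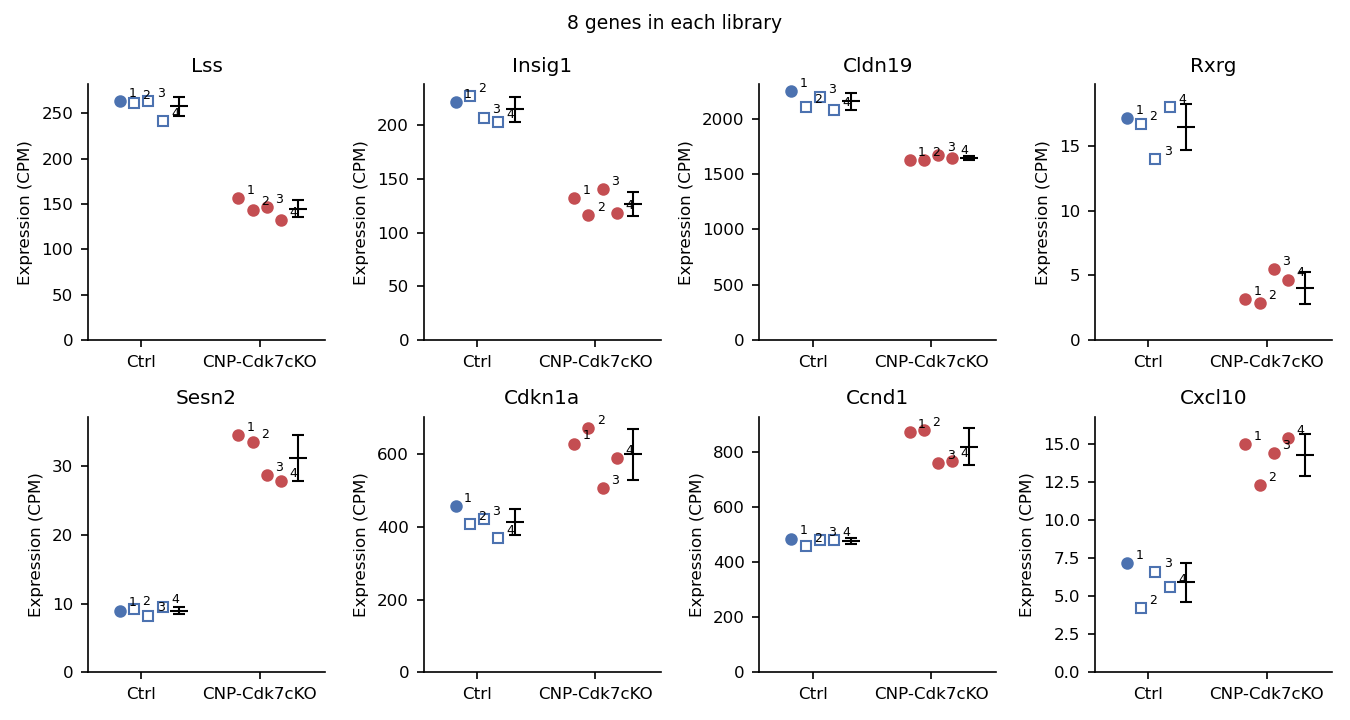
Expression in CPM (vertical axes, from 0) of 8 genes in each of the 4 Ctrl and 4 CNP-Cdk7cKO libraries, numbered by replicate; open squares are libraries with Y-linked counts, and black bars are mean ± SD. Lss, Insig1, Cldn19 and Rxrg are lower, and Sesn2, Cdkn1a, Ccnd1 and Cxcl10 higher, in every CNP-Cdk7cKO library than in any Ctrl library, Ctrl 1 included.

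Inflammatory cytokines and chemokines were higher in the knockout nerves, with 8 of 15 measured members up and 0 down (10 and 0 adjusted over the list alone). Cxcl10, an interferon-induced chemokine, rose from 5.91 ± 1.28 to 14.3 ± 1.38 CPM (SD, n = 4; log2 fold change 1.27 ± 0.15 SE, edgeR quasi-likelihood adjusted p = 0.00055). Csf1, the growth factor of macrophages, rose from 38.6 ± 2.87 to 61.4 ± 4.79 CPM (0.67 ± 0.07), and the adhesion gene Vcam1 (0.62 ± 0.09) and Lif (0.67 ± 0.11) rose too. The list median was 0.55, and camera called it (adjusted p = 2.05e-05), but not with an estimated correlation (adjusted p = 0.0939); 2 of the 8 rises still passed with Xist as a covariate, where the median was 0.68 under a wider standard error, and 5 members rose without CNP-Cdk7cKO 3. Macrophage markers rose in 7 of 18 members and fell in 2 (11 and 3 adjusted over the list alone). Trem2 (0.66), the fractalkine receptor gene Cx3cr1 (0.42) and the cathepsin gene Ctss (0.47) rose, and Lgals3 (-0.99) and Gpnmb (-0.69) fell, the latter named after its value was seen. Camera called the macrophage list (adjusted p = 0.00777), but not with an estimated correlation (adjusted p = 0.572), and 1 of its 9 calls passed with Xist as a covariate, where all 9 kept their sign and the list median went from 0.29 to 0.42. Fewer macrophage markers rose without Ctrl 1 or 2 (3 each), Ctrl 3 (2), CNP-Cdk7cKO 3 (2) or CNP-Cdk7cKO 4 (3), and 1 in place of 2 fell without Ctrl 3, Ctrl 4 or any CNP-Cdk7cKO library. Fibroblast markers rose in 4 of 17 members and fell in 0 (8 and 0 adjusted over the list alone): Osr2 (0.42), Col1a1 (0.25), Pdgfra (0.19) and Col15a1 (0.22). Camera called that list (adjusted p = 0.00777), but not with an estimated correlation (adjusted p = 0.111) and not without Ctrl 1 (adjusted p = 0.0515), and 0 of the 4 rises passed with Xist as a covariate, where the list median went from 0.16 to 0.20. In the fibroblast list 2 members rose without Ctrl 3 or CNP-Cdk7cKO 2, 7 rose without CNP-Cdk7cKO 4, and 3 rose and 2 fell without Ctrl 1. Endothelial markers had 0 of 18 members up or down by edgeR, also when adjusted over the list alone (camera adjusted p = 0.291), against 2 lower at an unadjusted p under 0.05 and 1 lower by each of DESeq2 and limma-voom and without Ctrl 1 or Ctrl 4, and 2 without CNP-Cdk7cKO 3; Cdh5 measured 131 ± 15.4 CPM in Ctrl and 123 ± 4.76 CPM in CNP-Cdk7cKO. Pericyte and smooth muscle markers had 1 rise (Cspg4, 0.25) and 2 falls (Pdgfrb, -0.25; Des, -2.35) among 13 members, perineurial markers 1 fall (Ntng1, -0.63) among 11 with a median of 0.06 and a mean of -0.06, and lymphocyte, mast cell and neutrophil markers 1 fall (the mast cell tryptase gene Tpsb2, -1.11) among 8. Adipocyte markers had 2 falls among 9 (Car3, -2.68, also abundant in muscle; Plin4, -2.60), erythroid markers 0 calls among 8 by edgeR, DESeq2 and limma-voom and 0 at an unadjusted p under 0.05, but 5 lower without Ctrl 1 and 4 lower with the first surrogate variable, and neuronal markers 1 rise (Tubb3, 0.42) and 1 fall (Uchl1, -0.29) among 8. Des is also a muscle gene, at 199.8 CPM in Ctrl 4 and 27.0 CPM in Ctrl 1, and the 3 calls of the pericyte and smooth muscle list were lost with Xist or the muscle markers as a covariate (Des log2 fold change -0.56 and -0.24). Adjusted over the list alone, perineurial markers had 2 falls and the other 5 lists the same counts. The tryptase call was lost whenever a library other than CNP-Cdk7cKO 3 was left out, and without CNP-Cdk7cKO 3, 4 members of its list fell. Perineurial falls numbered 2 without Ctrl 4, pericyte and smooth muscle falls 1 and adipocyte falls 1 without CNP-Cdk7cKO 1, and neuronal rises 0 without Ctrl 2 or CNP-Cdk7cKO 1. Camera called none of these 6 lists, with adjusted p-values of 0.58, 0.96, 0.0504, 0.0648, 0.304 and 0.691 in that order. With Xist as a covariate, a fit that rests on Ctrl 1, camera called the erythroid list higher (adjusted p = 0.00756, median 0.602).

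Stress response genes moved in part. In the integrated stress response list 5 of 25 members rose and 0 fell (6 and 1 adjusted over the list alone), namely Sesn2, Gdf15, the amino acid transporter gene Slc7a5 (0.39), Ddit4 (0.41) and Ppp1r15a (0.25), the last named after its value was seen. Sesn2 and Gdf15 are also p53 targets. Camera called the list (adjusted p = 0.00392), but not with an estimated correlation (adjusted p = 0.136), and 1 of the 5 rises passed with Xist as a covariate (list median 0.13 without it and 0.22 with it); without Ctrl 1, 1 member fell. In the unfolded protein response of the endoplasmic reticulum 4 of 21 members rose and 1 fell (8 and 1 adjusted over the list alone). The chaperone genes Hspa5 (0.18), Hsp90b1 (0.17) and Calr (0.19) and Creld2 (0.27) rose. Camera called this list (adjusted p = 0.0302), but not with an estimated correlation (adjusted p = 0.155), the replicate block (adjusted p = 0.0558), Xist (adjusted p = 0.154) or muscle (adjusted p = 0.131) as a covariate, in the female libraries alone (adjusted p = 0.21), or without CNP-Cdk7cKO 3 (adjusted p = 0.0644). Its 1 fall was lost whenever a library other than Ctrl 3 was left out. Among 24 immediate early genes 4 rose and 2 fell (5 and 2 adjusted over the list alone), with rises in Ier5 (0.47), Btg2 (0.63) and Junb (0.59) and a fall in Klf6 (-0.48). Camera called the list at an adjusted p of 0.0487, but not with an estimated correlation (adjusted p = 0.451), and the call also ended with the replicate block (adjusted p = 0.0707), with Xist or muscle as a covariate (adjusted p = 0.148 and 0.883), by limma-voom (adjusted p = 0.0579), with the 1 CPM filter (adjusted p = 0.0523), in the female libraries alone (adjusted p = 0.133), and without Ctrl 4, CNP-Cdk7cKO 1 or CNP-Cdk7cKO 3 (adjusted p = 0.0581, 0.0733 and 0.072). Of the immediate early genes 1 in place of 2 fell without Ctrl 1, Ctrl 2, Ctrl 3, CNP-Cdk7cKO 2 or CNP-Cdk7cKO 4. Of 18 targets of YAP and TAZ 2 rose (Ccn1, 0.51; Ajuba, 0.25) and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.291), and 1 rose whichever library was left out. Nuclear-encoded oxidative phosphorylation had 1 rise (Sdhc, 0.20) among 32 members and 0 adjusted over the list alone (camera adjusted p = 0.131), against 3 without Ctrl 4 and 0 whichever other library was left out. Cytosolic ribosomal protein genes had 2 rises (Rps2, 0.23; Rpl12, 0.22) among 37 and 1 adjusted over the list alone, and 1 when any Ctrl library or CNP-Cdk7cKO 3 was left out. Their median was 0.09, called by camera (adjusted p = 0.00465), but not with an estimated correlation (adjusted p = 0.87), with the muscle markers as a covariate (adjusted p = 0.344) or without CNP-Cdk7cKO 4 (adjusted p = 0.237). The 13 mitochondrially encoded mRNAs had 0 calls by edgeR, DESeq2 and limma-voom and 0 at an unadjusted p under 0.05 in edgeR, also when adjusted over the list alone (camera adjusted p = 0.84), and took 3.33 ± 0.09% of counts in Ctrl and 3.50 ± 0.13% in CNP-Cdk7cKO.

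Over all 37 lists, camera with its preset correlation called 10 higher and 8 lower. With a correlation estimated for each list it called 0, and fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes, called 16.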

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

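The tests of sex, Schwann cell share, Cre and muscle below were chosen after the results they bear on were seen, and the splits of the libraries before. Among 254 groups of 4 values examined, 13 held a library far from the other 3 (by the size of the gap to the nearest of them); chance gives about 1 in 20 groups. In Ctrl 1, Cspg4 stood at 167.22 CPM against 151.4 to 153.11 in the other controls, Xist at 295.02 CPM against at most 0.102, and the 4 Y-linked genes at 0 CPM against 92.27 to 105.88. In Ctrl 3, Rpl12 stood at 300.54 CPM against 283.26 to 285.48. In Ctrl 4, Lss stood at 241.95 CPM against 261.43 to 264.05, Ajuba at 44.129 against 52.823 to 54.603, and Myh1 at 74.459 against 11.639 to 19.832. In CNP-Cdk7cKO 2, Lmod2 stood at 0.43502 CPM against 0.098 to 0.155 and Vcam1 at 16.434 against 13.494 to 13.759. Igfbp2 was at 21.248 CPM in CNP-Cdk7cKO 3 against 24.99 to 25.605. In CNP-Cdk7cKO 4, Cyp51 was at 235.48 CPM against 249.49 to 250.96, Pisd at 144.95 against 132.38 to 133.04, and the Y-linked genes at 0.199 CPM against 0.

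In CNP-Cdk7cKO 23 of 25 cholesterol synthesis, 14 of 26 fatty acid synthesis and 12 of 26 myelin protein genes were lower and 20 of 26 p53 targets higher (camera adjusted p = 0.111, 0.111, 0.199 and 0.097 with an estimated correlation), and its libraries were all female against 1 female and 3 male controls. Cnp, whose locus carries Cre in the knockout, is among the 12 myelin protein genes. Sex cannot be told apart from the loss of Cdk7 by these libraries, since Ctrl 1 is the 1 female control: 73.91% of the cholesterol calls and 61.9% of the p53 calls held with Xist as a covariate, and Ctrl 1 lay nearer the male control mean in 80.83% of 1346 autosomal genes called between the male controls and the knockout libraries, but all 3 values rest on that library. A lower share of Schwann cells cannot be told apart for the cholesterol genes, and stays open for the myelin and fatty acid genes: 9 pan-Schwann markers had a median log2 fold change of -0.273 with 5 lower and 0 higher, against -0.192 for myelin proteins and -0.293 for fatty acid synthesis, and the cholesterol genes fell further by -0.168 (two-sided exact permutation p = 0.0571, smallest possible 0.0286). Against it, markers of other cells did not all rise, with differences in mean log2 CPM of 0.084 for fibroblasts, 0.13 for macrophages, -0.07 for endothelium, -0.158 for pericytes and -0.046 for perineurium, but these lay near or within the spread between libraries (two-sided exact permutation p from 0.1429 to 0.5714). Cre and the missing Cnp allele cannot be told apart from the loss of Cdk7, the difference named by the design, since 0 control libraries carried Cre, and all of these stay open.

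Skeletal muscle genes were lower in CNP-Cdk7cKO, and within groups 81.59% of their variance lay on 1 component, against a median of 49.2% for 1000 random lists. Muscle carried over at dissection in amounts that varied between nerves could give this, with a share 9.76 times as high in Ctrl 4 as in Ctrl 1. Members of other lists moved together as well. The estimated correlation was 0.81 for muscle markers, 0.909 for ribosomal proteins and 0.82 for mitosis genes. The single component thus does not separate carry-over from lower expression by the nerve itself. The difference also ran with sex or with Ctrl 1, the 1 female control: the list median went from -2.665 to -0.609 with Xist as a covariate and to -0.72 in the female libraries only, so sex stays open here too. A lower expression of these genes by the nerve itself was not tested.

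For the numbers of genes, the real split called 763 higher and 994 lower. The highest of the other splits called 2 in its larger direction and 0 in the other. Thus 1 of 35 splits reached each count, the smallest share that 35 splits allow, which makes chance in how libraries were grouped unlikely but does not exclude it. The other splits mix knockout and control libraries, so any difference between the groups, sex and muscle included, widens their spread and lowers their counts. For the number of gene lists called by camera chance cannot be excluded, since the real split called 18 and the highest other split 19, so that 2 of 35 reached it.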

How the results depend on the processing

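The comparison of female libraries alone was chosen after the data were seen; the other settings were planned. Cdk7 and Cnp fell past the threshold in every setting fitted, with log2 fold changes of -0.987 to -0.814 and -1.256 to -1.145 and adjusted p-values of at most 0.0374 and 0.000752. The 763 higher and 994 lower genes became 158 and 228 with the skeletal muscle covariate, 76 and 167 with the Xist covariate, and 40 and 77 in the female libraries only. Of these, 150 and 220, 70 and 162, and 37 and 76 were also called without the covariate or restriction. The standard error widened 1.56 times with the muscle covariate and 1.58 times with Xist by construction, as both covariates are correlated with group, and the female comparison has 1 control; other causes were not tested. RLE factors, TMM without muscle, erythroid, adipocyte and mitochondrial genes, both filters, DESeq2, limma-voom and the first surrogate variable gave 698 to 898 higher and 973 to 1186 lower genes. With the replicate block the counts were 682 and 926 and 16 lists were called. After the group mean of each gene was subtracted from its log CPM, same-number libraries correlated at 0.0089 to 0.127. By the same measure, 1 Ctrl library correlated best with the knockout library of its own number. These values show no clear pairing but do not exclude that the numbers pair libraries. Leaving out each library in turn gave 470 (without Ctrl 2; 500 without Ctrl 3) to 655 higher and 653 (without Ctrl 2) to 860 lower genes, Cdk7 at -0.941 to -0.814, Cnp at -1.196 to -1.145, and 16 to 21 lists. Camera with estimated correlation called 0 lists instead of 18, with fry calling 16; an allowance for correlated members is the alternative's own construction. The median of the skeletal muscle list reversed to 0.077 with the muscle covariate, which is built from those genes. That of the erythroid list went from -0.553 to 0.602 with Xist and 0.603 in the female libraries only. Both of these settings rest on Ctrl 1, where erythroid markers took 0.0737% of counts. They took 0.175% to 0.2131% in Ctrl 2 to 4 and 0.0979% to 0.1537% in the knockout libraries. Why Ctrl 1 was lower was not tested. A further 58 changes of sign were in results past the threshold in neither setting and were counted as unchanged. Of 121 named genes, 61 lost their call with the muscle covariate and 78 with Xist, against 4 with the replicate block and 11 with limma-voom. In simulated libraries of this size 14% of genes at the smallest planted change were recovered. The simulation held 50 planted genes at each fold, against 1757 genes called in the data. Fewer changed genes make the adjusted threshold stricter, so the share of small changes missed in the data is not known from it.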

Other observations

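The genes and families in this paragraph were chosen after their values were seen, and the gene length and GC tests of the next paragraph before. All 36 genes looked at kept their sign with Xist as a covariate, and 23 kept their call. Among those that fell were Aspa, which releases acetate from N-acetylaspartate, from 69.6 to 39.2 CPM (log2 fold change -0.83, edgeR adjusted p = 7.13e-05), Aacs (-0.63), Bdh1 (-0.57) and Acss1 (-0.45, call lost with Xist). Cldn11, a tight junction gene of myelinating glia, fell from 22.5 to 3.84 CPM (-2.55), and Mobp (-1.34) and Mapt (-0.84) fell too. Plekha4 (-0.70) fell, and the protease inhibitor gene Serpine2 rose from 314 to 556 CPM (0.83). Nfkb2 (0.52), Nfkbie (0.96) and Nfkbia (0.44) rose, as did Tnfaip2 (1.36) and the chemokine gene Cx3cl1, from 4.22 to 14.4 CPM (1.76). Trp53 itself rose from 77.5 to 102.3 CPM (0.40, call lost with Xist), with the p53 target Pidd1 (1.52) and Gtse1, a negative regulator of p53 (1.11). Pmel (-1.36), Mitf (-0.58) and Tyrp1 (-1.94, call lost with Xist) fell. Of 49 potassium channel subunit genes 11 fell, among them Kcna2 (-0.56), Kcna6 (-0.56) and Kcnh2 (-0.72), and 5 rose (camera p = 0.115, 0.104 with an estimated correlation; two-sided exact permutation p = 0.0571). Of 42 collagen genes 14 rose and 2 fell (camera p = 6.42e-05, 0.126 with an estimated correlation; two-sided exact permutation p = 0.0286), with 0 calls left with Xist. Of 35 spliceosomal protein genes 4 rose, Snrpa1 (0.75) most, and 0 fell (camera p = 0.000439, 0.0675 with an estimated correlation; two-sided exact permutation p = 0.0286), with 1 call left with Xist.

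Long genes may lose more transcript when Cdk7 is lost, given its part in transcription. Across 13696 protein-coding genes the fold change fell with gene length (Spearman rho -0.2013, and -0.1872 without Ctrl 4), and median lengths were 16.8 kb for higher, 39.2 kb for lower and 24.5 kb for other genes. The relation was as strong with exonic length (rho -0.2031), so it does not single out length on the genome. By library against the control mean, rho for length was strongest in CNP-Cdk7cKO 4, at -0.3074 against -0.0876 to -0.1328 in the other 3, and rho for GC was 0.3097 there against 0.0554 to 0.1134. For each control against the mean of the other controls, rho for length was -0.0516 to 0.0347. Their rho for GC was -0.0604 to -0.0376 in Ctrl 1, 2 and 4 but 0.1381 in Ctrl 3. That value exceeded those of CNP-Cdk7cKO 1 to 3, so a GC trend of this size was not particular to the knockout libraries. Library GC bias is a second candidate explanation: the fold change rose with GC content (rho 0.1974), and GC and length were themselves correlated (rho -0.3128). Each relation was smaller with the other held fixed (-0.1497 for length, 0.1446 for GC), so neither was excluded. With both trends removed the list medians were -0.418 for cholesterol synthesis, -0.289 for fatty acid synthesis, -0.153 for myelin proteins and 0.687 for p53 targets.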
